A study of Hydra viridissima with 5 samples.

How the data were processed

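Native DNA of whole Hydra viridissima polyps was sequenced in 5 ultralong nanopore runs, 1 of symbiotic and 4 of aposymbiotic clone 2 animals. Per the labels, polyps were kept at 24 °C, fed 3 to 4 times a week and taken 2 to 3 days after feeding, and the basecalling used Dorado's sup model for 5mCG and 5hmCG on R10.4.1 reads. Per the submitters' processing notes, minimap2 2.28 was used. The pileup program, its probability threshold, read filters and the assembly are not given in the sources used here. Samples were grouped by the condition in the labels, and aposymbiotic replicates were numbered in accession order, which pairs nothing.

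The deposited tables hold, for each CpG position of a library, whole-number counts of valid calls, 5mC calls, unmodified calls, calls of another modification and failed calls, with both strands combined. They also hold a deposited percent of valid calls that are 5mC. Checked on every row, valid calls equalled the sum of 5mC, unmodified and other calls, and the percent equalled the 5mC share to within 0.005 points. The tables have 18 columns and no header, so the layout was taken from the format and these checks. The other modification was taken as 5hmC because the labels name a model for 5mC and 5hmC. Probabilities below the unknown threshold appear as failed calls. They were 8.72% of valid plus failed calls in the symbiotic library and 9.37%, 8.74%, 8.80% and 9.37% in aposymbiotic replicates 1 to 4. Such filtering removes ambiguous calls and can shift low levels.

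The union held 5147380 CpG positions on 184 sequences, of which 19 reached 1000000 bp by their last CpG. A coverage minimum of 10 valid calls in every library, set before the data were examined, left 2481086 sites. It was met by 53.0% of the sites listed for the symbiotic library and by 80.1%, 87.9%, 91.1% and 83.7% of those listed for aposymbiotic replicates 1 to 4. The symbiotic depth therefore set which sites were tested. The levels are sums of 5mC calls over sums of valid calls. No 2 libraries were duplicates: over the 10 pairs, 1.67% to 7.04% of sites had the same number of valid calls.

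Sites were grouped into 2000-bp windows with at least 5 sites. A quasi-binomial logistic model compared the symbiotic counts with the aposymbiotic counts in each window. Its dispersion came from the 4 aposymbiotic libraries (3 residual degrees of freedom), was moderated across windows with limma 3.58.1 and was kept at 1 or above. The lone symbiotic library was assumed to vary like the aposymbiotic ones. Windows were called at a Benjamini-Hochberg adjusted p under 0.05 and a difference of at least 10 points. The same model was run on counts summed per sequence, and with each aposymbiotic library as the lone one. Single sites were tested with Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment. The genome-wide level was compared by an exact permutation test over the choice of the lone library. Intervals are 95% Wilson intervals and cover counting error only. They take each call as an observation, although calls from the same read are not independent.

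Named regions follow a rule fixed in advance: called windows with the symbiotic level outside the aposymbiotic range were merged across gaps of at most 1 window, and the 10 regions with the largest difference in each direction were named. Of 110 merged regions, 58 were higher and 52 lower. The named sequences are the 3 with the largest and the 3 with the smallest difference among those of at least 1000000 bp. The planned analysis of genes and gene features was not run, because no annotation with these sequence names was used here.

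The window test was tested on simulated data, with counts drawn for the 90225 real windows at an overdispersion of 1.5 and 200 windows changed. It recovered 28.4% of changes of 10 points, 86.6% of 20 points and 100% of 40 points, and called 0 of 90025 unchanged windows. In a further simulation the spread of windows at 5% to 95% was drawn from the distribution estimated there. There the prior over all windows took at least 1000000 degrees of freedom, against 37.9 on the real windows, so the shared spread weighed more. The test then called 158 of 90025 unchanged windows. With the dispersion prior fitted to the real windows at 5% to 95%, it called 2 of them. When only windows at 10% to 90% were changed, that prior recovered 3% of 100 changes of 20 points and 29% of 100 changes of 40 points, and the prior over all windows 75% and 99%. The Fisher routine was checked against scipy.

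Alternatives were coverage minimums of 5 and 20, an upper coverage limit of 3 times the median, 5mC plus 5hmC, thinning to equal depth, leaving out each aposymbiotic library, sequences of at least 1000000 bp, windows of 1000 and 5000 bp, at least 10 sites per window, other minimum differences, a logit shift, limma on log2 ratios with a pseudocount of 1, and edgeR 4.0.16 on methylated and unmethylated counts. Further alternatives were chosen after seeing the data and are named as such in the closing section. The analysis used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0, matplotlib 3.10.9 and R 4.3.3.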

Results

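CpG methylation was measured in the green hydra Hydra viridissima, a freshwater cnidarian that normally carries photosynthetic algae inside its endodermal cells, by nanopore sequencing of native DNA. Modified cytosines were called directly from the current signal of unconverted molecules. The series holds 1 library from symbiotic animals of clone 2 and 4 libraries from aposymbiotic animals, which lack the algae, of the same clone. Each library was 1 MinION run on DNA from a pool of 800 to 1000 whole polyps, buds and testes included. The symbiotic group had no replicate, so no difference below has a replicate check on that side. The labels do not say that the 4 aposymbiotic libraries came from separate cultures or extractions, so their SD measures the spread between these libraries, which may be technical. The permutation, window and sequence p-values rest on that spread, for windows and sequences through a dispersion shared across them. Fisher's p-values for single sites hold the sampling of calls only. The symbiotic library held 54221828 valid calls, a median of 10 per listed site, and the aposymbiotic libraries held 85855319, 108114154, 126440068 and 91398912, with medians of 16, 21, 24 and 17. Coordinates are 1-based on the sequences named in the deposited tables, whose build is not given in the sources used here. No gene annotation was used, so no region below is assigned to a gene, exon or intron.

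The methylome of the green hydra was a mosaic of methylated and unmethylated stretches in both kinds of animals. In the symbiotic library 21.1% of the 90225 windows of 2000 bp were methylated at 50% or more, against 21.0% ± 0.0522 (SD, n = 4) in the aposymbiotic libraries. Windows under 10% made up 71.0% in the symbiotic library and 71.2% ± 0.148 (SD, n = 4) in the aposymbiotic ones, and the windows between made up 7.94% and 7.87% ± 0.0998 (SD, n = 4). These shares depend on which sites qualify. At a coverage minimum of 20 methylated windows made up 6.66% in the symbiotic library and a mean of 6.54% in the aposymbiotic ones. At a minimum of 5 they made up 23.4% and 23.3%. In the main setting the symbiotic share of methylated windows lay 0.0809 percentage points above the aposymbiotic mean. That gap shrank to 0.0216 points when every library was thinned to 10 calls per site. Within methylated windows the 5mC level, the percent of valid calls that were 5-methylcytosine, was 88.7% in the symbiotic library and 88.5% ± 0.583 (SD, n = 4) in the aposymbiotic libraries. Within unmethylated windows it was 0.452% and 0.438% ± 0.0254 (SD, n = 4).

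**Figure D1:**
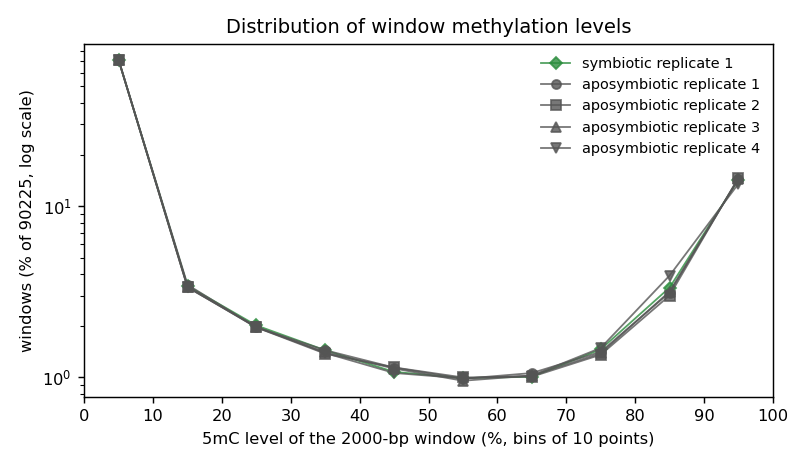
Share of the 90225 windows of 2000 bp in each 10-point bin of 5mC level (y axis, percent of windows, log scale; x axis, level in percent) for the symbiotic library (green) and the 4 aposymbiotic libraries (grey). The symbiotic curve has 71.0% of windows in the lowest bin, 3.34% from 80 to 90 and 14.3% in the highest, and aposymbiotic replicate 4 stands apart in the last 2 bins, with 3.93% and 13.5%.

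Single windows kept their class across the libraries. Of the 90225 windows, 87653 (97.1%) were in the same class in all 5 libraries: 18461 were always methylated, 63384 always unmethylated and 5808 always between. Only 1 window was methylated in one library of a pair and unmethylated in the other, over all 10 pairs, in the symbiotic library and aposymbiotic replicate 2. Window levels of the symbiotic library correlated with those of the aposymbiotic libraries at Pearson r from 0.9972 to 0.9977, and those of the aposymbiotic libraries with each other at 0.9976 to 0.9986. Spearman's rho was 0.844 to 0.868 for the symbiotic pairs and 0.827 to 0.853 for the aposymbiotic pairs. These correlations are across windows, which are not independent replicates. At equal depth the mean absolute difference between window levels was 1.09 to 1.20 points for the symbiotic pairs and 1.01 to 1.20 points for the aposymbiotic pairs, so the ranges overlapped.

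Methylated windows were poor in CpG sites. In the aposymbiotic libraries pooled, the 18875 methylated windows had a median of 6 CpG sites per kb (quartiles 4 and 8.5), and the 64213 unmethylated windows had 19.5 (quartiles 15.5 and 25). The 7137 windows between had a median of 11 CpG sites per kb. In the symbiotic library the medians were 6, 19.5 and 11.5 CpG sites per kb for the same classes. Density and level were negatively related across windows, with Spearman's rho -0.56 in the aposymbiotic libraries and -0.60 in the symbiotic library. Windows are not independent replicates, and no test was made of this relation.

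The first comparison asked whether symbiotic and aposymbiotic animals differed in the genome-wide level of CpG methylation. Over the 2481086 CpG sites with at least 10 valid calls in every library, the symbiotic level was 9.52% (95% Wilson interval 9.51% to 9.53%, counting error only). The aposymbiotic level was 9.17% ± 0.203 (SD, n = 4), with 9.31%, 9.33%, 9.16% and 8.89% in replicates 1 to 4. The symbiotic library lay 0.347 points above the aposymbiotic mean and above each aposymbiotic library. The difference was not past the test (two-sided exact permutation p = 0.4), and 5 libraries with 1 in the lone group cannot give a p below 0.2. The difference dropped to 0.0113 points, 9.85% against 9.84% ± 0.0635 (SD, n = 4), when every site was thinned to 10 calls in each library (two-sided exact permutation p = 1).

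**Figure D2:**
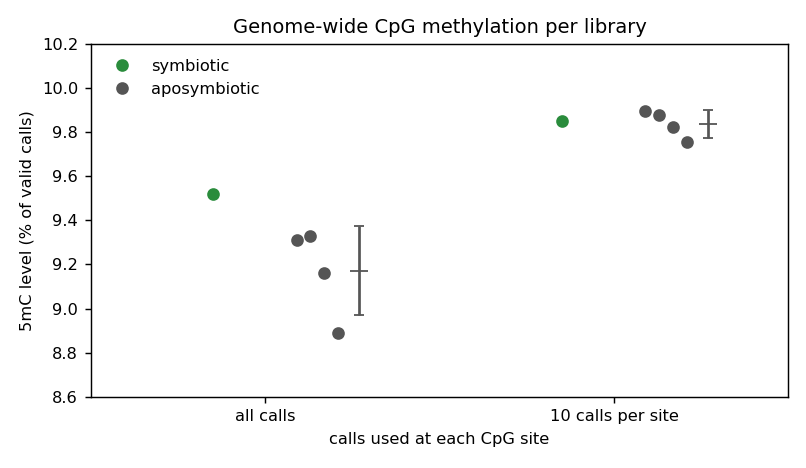
Genome-wide 5mC level in percent of valid calls (y axis, starting at 8.6) for each library, with all calls and with 10 calls drawn per site and library (x axis). Points are libraries, aposymbiotic replicates 1 to 4 from left to right, and bars are the aposymbiotic mean ± SD. The symbiotic point, 9.52% with all calls, falls inside the aposymbiotic range at 9.85% with 10 calls per site.

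The excess passed the test on no large sequence. Over the tested sites, on all 19 sequences of at least 1000000 bp the symbiotic level lay above the aposymbiotic mean, by 0.164 to 0.517 points, and on 12 of them it lay outside the range of the aposymbiotic libraries. In 2 settings chosen after seeing the data, it lay above on 8 of the 19 at equal depth, with differences from -0.0783 to 0.178 points, and on 17 over all calls with no coverage minimum, with -0.156 points on ptg000022l and -0.0604 on ptg000014l. None of the 19 was called, by the quasi-binomial model with limma's moderated dispersion (smallest adjusted p = 0.432), and none had an unadjusted p under 0.05. The moderated dispersion was the same on all 19, at 263, so the shared prior replaced the spread of each sequence. With the upper coverage limit none was called either, but the same model gave 1 of them, ptg000001l, an unadjusted p of 0.04996. The 3 with the largest difference were ptg000003l, at 10.18% in the symbiotic library and 9.66% ± 0.296 (SD, n = 4) in the aposymbiotic ones, ptg000009l, at 10.003% and 9.49% ± 0.205 (SD, n = 4), and ptg000011l, at 10.5% and 10.04% ± 0.276 (SD, n = 4). The 3 with the smallest were ptg000018l, at 7.64% and 7.46% ± 0.298 (SD, n = 4), ptg000020l, at 7.82% and 7.66% ± 0.142 (SD, n = 4), and ptg000007l, at 9.42% and 9.25% ± 0.534 (SD, n = 4). Levels differed more between sequences than between libraries: the aposymbiotic mean ran from 1.78% on ptg000022l to 11.96% on ptg000005l. On ptg000022l 23040 of 139669 sites were tested, and its mean was 2.53% with the upper coverage limit and 4.13% over all calls, where ptg000005l had 13.07%.

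The second comparison asked which regions differed between the symbiotic and the aposymbiotic libraries. Of the 90225 windows, 142 were called, 71 higher and 71 lower in the symbiotic library. The even split depended on the setting, with 177 higher and 93 lower when no minimum difference was set and 126 and 84 at a coverage minimum of 5. Without aposymbiotic replicate 1, 2, 3 or 4 the test called 263, 234, 225 and 244. In those leave-one-out fits the dispersion prior had at least 1000000 degrees of freedom, against 37.9 in the main fit. The shared prior then almost replaced the spread of each window. On simulated data in which the spread differed between windows the test called 158 of 90025 unchanged windows. That fit also had at least 1000000 prior degrees of freedom, so the 158 cannot be set directly beside the 142. The 142 called windows lay on 19 sequences, and in all 142 the symbiotic level was outside the aposymbiotic range. The calling rule makes that likely for false calls too, because it sets the difference against the spread of the same 4 libraries. The median size of the difference was 19.1 points. The regions named below have the largest differences among these windows, so their sizes are likely overstated. None went from unmethylated in the aposymbiotic mean to methylated in the symbiotic library, or back. Instead 127 of the 142 (89.4%) had an aposymbiotic mean between 10% and 90%, as did 14.5% of all windows tested. This was not particular to the symbiotic library. Of its called windows with both neighbours tested, 95 of 108 had such a mean. With aposymbiotic replicates 1 to 4 as the lone library, 89 of 131, 54 of 57, 45 of 46 and 32 of 36 had one over the other libraries.

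The region with the largest positive difference was ptg000004l from 4798001 to 4802000, with 66 tested CpG sites. Its level was 66.4% in the symbiotic library and 23.2% ± 5.52 (SD, n = 4) in the aposymbiotic libraries (smallest adjusted p = 3.75e-11, 13.1 symbiotic calls per site). It borders a block that was nearly fully methylated in all 5 libraries. The adjusted p-values of the named regions take each call as an observation, although calls from the same read are not independent. With the calls of each window counted per read instead, a setting chosen after seeing the data, 0 of the 20 named regions were called. On ptg000020l from 10342001 to 10344000 the level was 76.4% against 37.1% ± 5.95 (SD, n = 4; adjusted p = 5.61e-07), and on ptg000014l from 3080001 to 3082000 it was 77.0% against 39.7% ± 5.84 (SD, n = 4; adjusted p = 4.21e-07). The region of ptg000022l from 3910001 to 3914000 had 56.7% against 19.0% ± 10.8 (SD, n = 4; smallest adjusted p = 0.000586), and its difference of 37.7 points, on 14 sites, was 18.3 at a coverage minimum of 5, when 91 sites qualified. The other 6 of the 10 largest positive differences were at ptg000009l from 7130001 to 7132000 and from 110001 to 114000, ptg000020l from 10858001 to 10860000, ptg000012l from 6546001 to 6548000 and from 14100001 to 14102000, and ptg000017l from 388001 to 392000. Over all 10, the symbiotic library lay 28.4 to 43.2 points above the aposymbiotic mean, and the aposymbiotic SD was 5.52 to 12.1 points. The difference of 31.2 points at ptg000012l from 6546001 to 6548000 rested on 9 sites. Without aposymbiotic replicate 4, when 19 sites of that window qualified, it was 8.17 points and not called, and at a coverage minimum of 5 it was 6.39 points on 30 sites and not called.

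The region with the largest negative difference was ptg000005l from 20448001 to 20452000, with 57 tested CpG sites. Its level was 44.4% in the symbiotic library and 81.4% ± 8.33 (SD, n = 4) in the aposymbiotic libraries (smallest adjusted p = 6.12e-07, 12.8 symbiotic calls per site). This adjusted p and those of the other lower regions also take each call as an observation, with the limit given above. The window of ptg000014l from 7426001 to 7428000 was at 0.840% in the symbiotic library, on 11 sites and 119 calls, against 28.9% ± 5.20 (SD, n = 4; adjusted p = 7.96e-05). Its difference of -28.0 points was -14.6 at a coverage minimum of 5, when 37 sites qualified, and was still called. On ptg000009l from 13566001 to 13568000 the level was 23.1% against 51.0% ± 8.28 (SD, n = 4; adjusted p = 1.18e-05). The longest region was ptg000013l from 7162001 to 7176000, with 7 called windows and 257 sites, at 24.1% in the symbiotic library and 50.5% ± 13.2 (SD, n = 4) in the aposymbiotic libraries (smallest adjusted p = 0.000679). The aposymbiotic libraries themselves ran from 34.8% to 66.7% there. The other 6 of the 10 largest negative differences were at ptg000012l from 9540001 to 9542000, ptg000004l from 11342001 to 11344000, ptg000014l from 2638001 to 2640000, ptg000056l from 512001 to 514000, ptg000017l from 15268001 to 15272000 and ptg000005l from 1844001 to 1846000. Over all 10, the symbiotic library lay below the aposymbiotic mean by 24.7 to 36.9 points, with aposymbiotic SDs of 3.03 to 13.2 points.

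**Figure D3:**
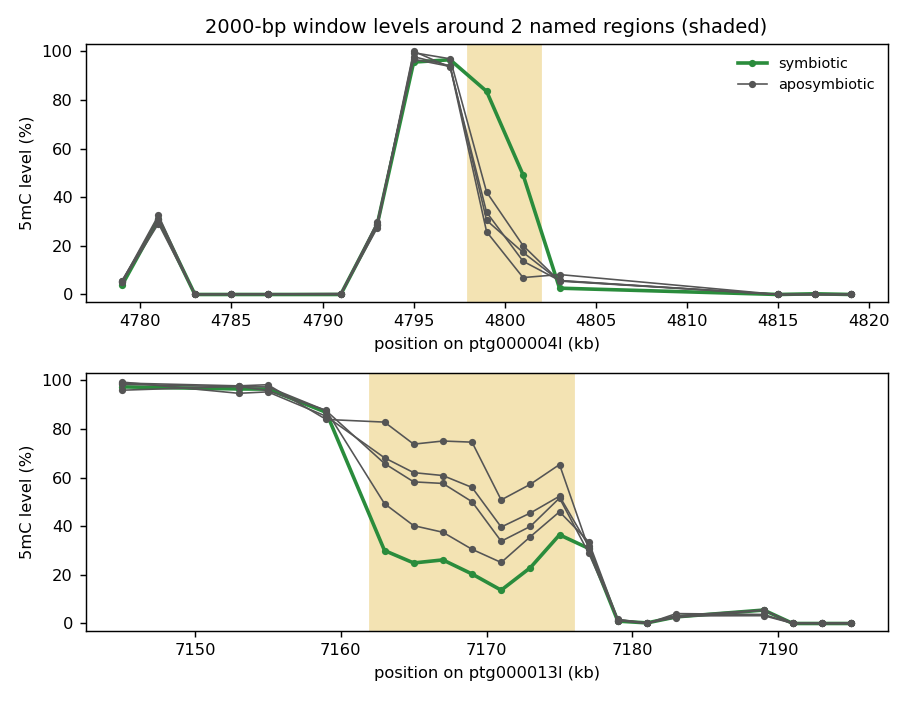
5mC level in percent (y axis) of 2000-bp windows along ptg000004l and ptg000013l (x axis, position in kb) in the symbiotic library (thick green line) and the 4 aposymbiotic libraries (thin grey lines), with the named region shaded. On ptg000004l the symbiotic line stands above the grey lines at the side of a methylated block, and on ptg000013l it stands below them while the grey lines there run from 25.1% to 82.8% over windows and libraries.

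The number of called windows was not above what an aposymbiotic library gave. With each aposymbiotic library in turn as the lone one against the other 4 libraries, the same model called 175, 74, 61 and 47 windows for replicates 1 to 4, against 142 for the symbiotic library. With 5 splits in all, a share under 0.05 cannot be reached. The splits are also not like for like. With an aposymbiotic library as the lone one, the symbiotic library helps to set the dispersion. The lone libraries differ in depth, and the prior had 37.9 degrees of freedom in the symbiotic split and 20.3 to 31.5 in the others. At an unadjusted p under 0.05 and at least 10 points the symbiotic library gave the most windows, 621 against 575, 359, 329 and 477, and also at equal depth, 360 against 324, 201, 142 and 270. With the dispersion prior from windows at 5% to 95%, chosen after seeing the data, it did not, at 336 against 363, 206, 177 and 286. With that prior at equal depth it gave the most again, 301 against 269, 138, 105 and 216. Fewer windows were called by other tests, 0 by limma on log ratios and 11 by edgeR's quasi-likelihood test, which gave 258 and 492 at the unadjusted threshold. With the calls of a window counted as one observation per read, a setting chosen after seeing the data, 0 windows and 0 of the 20 named regions were called, and 12 windows were left at the unadjusted threshold. On calls thinned to equal depth the main model called 0. The loss of calls there was not a loss of difference: over the same windows, the differences of the 20 named regions at equal depth were 89.4% to 133.8% of the reported ones, with a median of 99.8%. The thinned calls were drawn from the same calls, so these values are no independent check of the differences. Of the 20 named regions, 5 were still called by edgeR (ptg000004l from 4798001, ptg000020l from 10342001, ptg000014l from 3080001 and from 7426001, and ptg000005l from 20448001), and 0 by limma on log ratios or at equal depth. With 5000-bp windows, which also take in the sequence beside a region, 17 of the 20 were no longer called and the median difference was 48.98% of the reported one. For 5mC plus 5hmC 7 were no longer called, with differences of 96.6% to 103.2% of the reported ones.

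**Figure D4:**
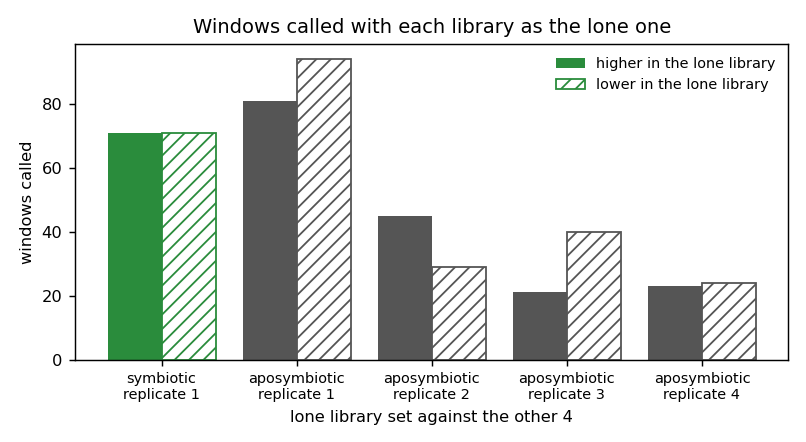
Number of windows called (y axis, from 0) with each library as the lone one against the other 4 (x axis), higher in the lone library (filled bars) and lower (hatched bars). The symbiotic library gave 71 and 71, and aposymbiotic replicate 1 gave 81 and 94.

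The third comparison took single CpG sites. None of the 2481086 sites was called by Fisher's exact test with Benjamini-Hochberg adjustment at 25 points or more. The smallest p was 3.3e-06, with an adjusted p of 1. This test compares these libraries and not the conditions, since the reads of a library are not replicates. At an unadjusted p under 0.05, 3109 sites differed by 25 points or more in the symbiotic library from the summed aposymbiotic ones. Each aposymbiotic library against the other 3 gave 2666, 1647, 1404 and 3367 such sites. At a minimum of 50 points the symbiotic library gave the most, 81 against 19, 3, 0 and 24. It also did at a coverage minimum of 20, with 102 against 86, 49, 15 and 71. Its median depth was the lowest, 10 calls per listed site against 16, 21, 24 and 17. Low depth gives large differences more often by sampling alone. The symbiotic library was also set against 4 summed libraries, and each aposymbiotic one against 3. No count at 50 points was made at equal depth, so the excess at 50 points cannot be told apart from an effect of depth. Between single libraries at equal depth, pairs with the symbiotic library gave 1007 to 1184 sites at 25 points or more and aposymbiotic pairs 956 to 1133. At a site with at least 90% in the aposymbiotic libraries, simulated losses of 25 points were recovered at 0.5% of 200 sites, losses of 50 points at 49% and losses of 75 points at 94%.

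Calls taken as 5-hydroxymethylcytosine, the oxidised form of 5-methylcytosine, were rare. They made up 0.158% of valid calls in the symbiotic library and 0.193% ± 0.0766 (SD, n = 4) in the aposymbiotic libraries, a difference inside the aposymbiotic range of 0.144% to 0.307% (two-sided exact permutation p = 0.8; the smallest possible is 0.2). In methylated windows the share was 1.01% against 1.26% ± 0.539 (SD, n = 4), and in unmethylated windows 0.0598% against 0.0755% ± 0.0295 (SD, n = 4). Aposymbiotic replicate 4 had the highest share in each class, and without it (a setting chosen after seeing the data) the symbiotic share over all windows lay above the aposymbiotic mean, by 0.00277 points, as did that of methylated windows, at 1.01% against 0.997% ± 0.159 (SD, n = 3). No unmodified control was used, so these are called shares and not measured amounts.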

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

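The splits and the thinning to equal depth were planned before the data were examined, all other tests of explanations in this part were chosen only after the result was seen, and what each test would show was written after the result in every case. Dixon's test over the 4 aposymbiotic libraries was run on 37 measures and singled out 2, where chance gives about 1 in 20, or 1.85. Aposymbiotic replicate 4 stood far above the others in 5hmC calls of unmethylated windows, at 0.120% against 0.0631%, 0.0589% and 0.0605%. The same library stood below the others in the 5mC level of the 30 CpG-dense sequences (30 or more CpG sites per kb, up to 664320 bp long), at 0.749% against 0.796%, 0.801% and 0.795%.

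A signal outside the tested sites lay at the start of ptg000155l. Over positions 1 to 1000, with 87 CpG sites, the symbiotic library had a depth of 0.865 relative to the 19 large sequences, and the aposymbiotic libraries had 0.0329, 0.0395, 0.0580 and 0.0899. The symbiotic 5mC level there was 72.5% (95% Wilson interval 69.3% to 75.5%, 789 calls), with 8.37% of calls as 5hmC. The aposymbiotic libraries, on 47 to 137 calls, had 5mC levels of 19.7% to 34.0% and 51.1% to 76.6% of calls as 5hmC. These are 9.07 calls per site in the symbiotic library and 0.540 to 1.57 in the aposymbiotic ones, so each level rests on few reads. Calls from the same read are not independent, so the interval is too narrow. From position 1001 onward the sequence was unmethylated in every library, and the depths were the other way round, 0.131 in the symbiotic library against 0.423 to 1.33.

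The first pattern weighed is the 142 windows called between the symbiotic and the aposymbiotic libraries. Of the 5 splits, 2 gave as many calls, the real one included, and the highest of the others was 175, but with 5 splits a share under 0.05 cannot be reached. The splits also differ in depth and in the libraries that set the dispersion. A candidate explanation is that runs vary more at intermediate levels than the shared dispersion prior allows. The test called 158 of 90025 unchanged windows when spread was simulated to differ between windows. That fit leaned more on the shared prior than the real one, with at least 1000000 prior degrees of freedom against 37.9. It therefore cannot say how many of the 142 are such calls. With the prior taken from windows at 5% to 95%, 0 windows were called (336 at an unadjusted p under 0.05 and at least 10 points), which decides nothing, because that setting recovered 3% of simulated changes of 20 points and 29% of 40 points in windows at 10% to 90%. A difference between symbiotic and aposymbiotic animals stays open as well, since the lowest distance of the symbiotic library from an aposymbiotic one at equal depth, 1.09 points, lay within the 1.01 to 1.20 points between aposymbiotic libraries, and a difference in few windows would not move that mean.

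The second pattern is the higher genome-wide level of the symbiotic library. Differences in depth between sites of high and low methylation could produce it, because a sum over calls weights sites by depth: at equal calls per site the difference was 0.0113 points, against an aposymbiotic SD of 0.203 points for the level with all calls. A gain of methylation over the tested sites of the size seen, 0.347 points, is argued against by the mean of site levels, which was 9.85% in the symbiotic library and 9.84% ± 0.0641 (SD, n = 4) in the aposymbiotic ones, a difference of 0.0113 points. Equal calls per site also weight every site alike, so the equal-depth difference and that of the site levels are the same evidence. They are not separate tests. With 1 symbiotic library a smaller difference between the animals stays open.

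The third pattern is the low depth of 111 CpG-poor sequences (under 9 CpG sites per kb) in the symbiotic library. Summed over them, depth relative to the large sequences was 47.2 in the symbiotic library and 230.5 ± 66.3 (SD, n = 4) in the aposymbiotic ones, a symbiotic to aposymbiotic ratio of 0.205. A loss of short molecules of every kind from the symbiotic library stays open: of the other sequences under 30000 bp, the 18 CpG-dense ones had a mean relative depth of 0.437 (aposymbiotic libraries 0.174 to 0.771) and the 15 others 0.441 (0.224 to 0.773), but the length of a sequence is not that of the DNA molecules. A difference between symbiotic and aposymbiotic animals cannot be told apart from a difference between runs, because there is 1 symbiotic library and the smallest exact permutation p is 0.2.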

How the results depend on the processing

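The genome-wide difference kept its direction under every alternative tried, from 0.0113 points at equal depth to 0.362 on sequences of at least 1000000 bp, and 0.263 to 0.393 with one aposymbiotic replicate left out. No exact permutation test here can go below 0.2 (0.25 with 3 aposymbiotic libraries). Counts of called sites (0) and called sequences (0) did not move under any alternative run for them. For sites this is no sign of stability. The main site test recovered 0.5% of 200 simulated losses of 25 points, and 10 calls against 10 can detect still less. The count of called windows, 142 as reported, depended on the setting. It was 3 at a coverage minimum of 20, 59 for 5mC plus 5hmC, 0 at equal depth, 295 for 1000-bp and 9 for 5000-bp windows, 270 with no minimum difference, 69 at 20 points, 0 with limma and 11 with edgeR. Leaving out aposymbiotic replicate 1, 2, 3 or 4 gave 263, 234, 225 and 244. Among alternatives chosen after seeing the data, it was 0 with the dispersion prior from windows at 5% to 95%, 0 with one observation per read, 224 against aposymbiotic replicates 1 and 4 alone and 312 against replicates 2 and 3 alone. Fewer qualifying windows (6513) explain part of the drop at a minimum of 20. The weight of the shared dispersion prior also changed with the setting. Its degrees of freedom were 37.9 in the main fit and 2.42 at equal depth. They were at least 1000000 with a replicate left out, against a pair of replicates and with 1000-bp windows. The higher counts in those settings are therefore no sign of robustness. The causes of the changes were otherwise not tested beyond the weighing above. The highest count with an aposymbiotic library as the lone one, 175, fell to 0 with that prior and to 0 at equal depth, both chosen later. The excess of methylated windows moved from 0.0809 to 0.0216 points at equal depth (chosen later), and the CpG density ratio of methylated to unmethylated windows from 0.308 to 0.263 with 5000-bp windows. No named region changed direction. Of the 20, those no longer called numbered 17 with 5000-bp windows, where 14 differences moved by over 1.5 times. At a coverage minimum of 5, 3 moved as much (their values stand above) and 2 lost the call. Without aposymbiotic replicate 4, 1 lost call and difference. Calls were lost with differences kept within 1.5 times for 7 for 5mC plus 5hmC, 1 with 1000-bp windows and 20 at equal depth. Calls were also lost for 15 with edgeR, and for 20 each with limma, with the later prior and per read. Those tests use the same levels, so their differences are the reported ones by construction. At equal depth (chosen later for sequences) ptg000003l and ptg000018l turned to -0.000433 and -0.0274 points. Without aposymbiotic replicate 4 (also later) the 5hmC difference turned to 0.00277 points, and without the others it was as low as -0.0515. At a coverage minimum of 20 none of the 20 regions had a value. The analysis by gene feature was not run. No paired analysis was possible because the symbiotic group has 1 library and the replicate numbers only name samples. The symbiotic depth, a median of 10 calls per site, limits every comparison.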

Other observations

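The measures in this part were chosen after seeing the data. Methylated DNA of the green hydra formed short blocks. With the calls of all 5 libraries summed, 11122 runs of 1000-bp windows at 50% or more reached 2000 bp on the 19 large sequences, with a median length of 4000 bp (quartiles 2000 and 8000). Runs of any length covered 24.4% of the 301882683 bp. The longest lay on ptg000019l from 1005001 to 1074000, 69000 bp with 517 CpG sites, at 89.5% in the symbiotic library and 91.1% to 93.5% in the aposymbiotic ones. The next lay on ptg000004l from 10810001 to 10876000, at 94.7% in the symbiotic library and 93.1% to 95.5% in the aposymbiotic ones. Single sites were also mostly at the extremes: 8.77% of symbiotic sites were at 80% or more, 88.7% at 20% or less and 2.56% between, with 2.59% to 2.77% between in the aposymbiotic libraries.

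Of the called windows with both neighbours tested, 24 of 108 (22.2%) lay between a methylated and an unmethylated neighbour, and of the 95 among them whose aposymbiotic mean was between 10% and 90%, 23 (24.2%) did. The share was 44.8% of the 9006 other windows with such a mean and 14.3% of all windows, and the difference was not tested. With aposymbiotic replicates 1 to 4 as the lone library the shares of all called windows were 16.8%, 15.8%, 21.7% and 22.2%. Of the 142 windows called for the symbiotic library, 13 were also among the 350 called for at least 1 aposymbiotic library.

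Sequences under 1000000 bp differed in depth between runs. The CpG-dense sequences (30 or more CpG sites per kb) had a mean depth relative to the large sequences of 1.29 in the symbiotic library and 1.59, 0.533, 0.565 and 1.505 in aposymbiotic replicates 1 to 4. Replicates 1 and 4 were thus alike, as were 2 and 3. Failed calls paired in the same way, and so did ptg000022l over all calls, at 3.63%, 4.76%, 4.57% and 3.59% in replicates 1 to 4. The genome-wide level did not. The aposymbiotic libraries may therefore not be exchangeable, and the reason was not tested. The sequence ptg000015c had relative depths of 3.45 in the symbiotic library and 3.44, 1.499, 1.39 and 3.72 in the aposymbiotic ones, with 5mC levels of 0.510% and 0.523% to 0.565%. Of the 111 CpG-poor sequences, 109 had a symbiotic relative depth below that of each aposymbiotic library. Among them, 58 ended between 15 and 17 kb, and this held in all 58. On ptg000066l it was 6.94 in the symbiotic library and 32.4, 19.5, 22.7 and 19.1 in the aposymbiotic ones. The 5mC level of the CpG-poor class was 0.0507% in the symbiotic library and 0.0408% ± 0.00832 (SD, n = 4) in the aposymbiotic ones. The sequences ptg000028l and ptg000172l were at 18.1% to 19.5% in all libraries.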
